A study of Rattus norvegicus with 12 samples.

How the data were processed

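Gene expression was measured in testis RNA of prepubertal male Sprague-Dawley rats with Affymetrix whole-genome rat arrays, on which each gene is read by 1 or more probe sets placed mainly toward the 3′ end of its transcript. The 12 arrays fell into 4 groups of 3: casein diet, casein diet with infused estradiol, soy protein isolate diet, and soy protein isolate diet with infused estradiol. Per the labels, diets were given from postnatal day 21 to 33, estradiol was infused under the skin at 10 µg per kg per day by osmotic minipump, and testes were collected on postnatal day 34 and frozen. Total RNA was labelled with biotin by in vitro transcription. The deposited values were log2 probe set intensities made with GCOS, the Affymetrix operating software, which the authors named without a version. The background correction, the summarisation of probes and any normalization between arrays were not given in the sources used here. The log scale was read from the values themselves, which ran from about 3 to 15 in every array. Whether each array held the RNA of a separate animal was not given either, so all p-values measured only the spread between these samples.

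The file held 31099 probe sets in 12 columns, all of which were used. The 57 Affymetrix control probe sets were kept out of the tests and examined on their own. A rule set before the data were examined called for quantile normalization if the lower quartiles, medians or upper quartiles of the arrays differed by more than 0.15 log2. They differed by 0.164, 0.069 and 0.183, so quantile normalization was applied, and the deposited values without it became an alternative. After the 30% of probe sets with the lowest means were left out, below 5.69 log2, 21729 probe sets of 11777 genes were tested. Gene symbols came from the platform annotation, in which 20832 probe sets had 1 symbol, 436 had several and 9831 had none. Of those with 1 symbol, 20764 were matched by Entrez ID to the rat gene table and 0 of these symbols had changed. A probe set with several symbols was taken to name no gene. Fshr had no probe set carrying its symbol alone and was not analysed here, and those of Esr1, Esr2 and Pgr lay below the level of the filter.

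All 4 groups entered 1 linear model in limma 3.58.1 under R 4.3.3, with moderated tests from eBayes with a mean-variance trend and 8 residual degrees of freedom. Each of 7 comparisons was adjusted by the Benjamini-Hochberg method over the probe sets tested, and a probe set was called at an adjusted p under 0.05. The comparisons were soy with casein, estradiol with none on each diet, soy with casein under estradiol, soy with estradiol on casein, both treatments with neither, and the interaction, which is the estradiol effect on soy minus that on casein. The median standard error of a log2 difference was 0.092, and 0.131 for the interaction. The number of arrays limits this precision. An exact test of 3 arrays against 3 cannot give a two-sided p under 0.1. On simulated data for soy with casein over 21729 probe sets, the procedure recovered 68.0% of 97 probe sets changed by 0.5 log2 and 95% of 100 changed by 1 log2, and 3 of 164 calls were false. The simulated noise was drawn independently for each probe set, without variation shared between genes. The share of false calls in the real arrays may therefore differ.

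The named genes followed a rule fixed in advance. In each comparison it started from the called probe sets with 1 symbol. Except in the interaction, the 2 groups of 3 arrays were also required not to overlap (chance gives 10% for 3 against 3). Among these probe sets the rule took the 10 genes with the largest rise and the 10 with the largest fall. Where fewer than 5 passed in a direction it took the 5 genes with the smallest unadjusted p, given as values. It added the 3 members with the smallest p of each gene list and 15 fixed genes of the steroid hormone and gonadal axes, and the text shortens each part from the end of its ranking. Exceptions are marked as chosen after their values were seen.

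The 25 gene lists held markers of testicular and contaminating cell types and genes of hormone, lipid, stress and cell division pathways. They were tested with camera in limma at a preset correlation between genes of 0.01, on the probe set of each gene with the highest mean. camera sets a list against all other genes, so where many genes move a list can change and still not pass. The same test with the correlation estimated from the data, and fry, which tests whether a list's genes move on balance in 1 direction, stood beside it. List p-values were adjusted over the 25 lists of a comparison. Members that passed are counted over all probe sets and adjusted over the list alone. Correlations of fold changes are across genes, which are not independent replicates. The groups, the comparisons, the lists, the rule for named genes and the alternatives were set before the data were examined, except for 1 alternative that left out 2 arrays with transcripts of neighbouring tissues. The other alternatives were the deposited values, centring each array on its median, no filter or a filter of 50%, eBayes without a trend or with robust estimation, the groups of a comparison alone, the replicate number as a block, leaving out each array, a fold over 1.5 with an unadjusted p under 0.05, 1 probe set per gene, and the mean over a gene's probe sets for lists. Figures were drawn with matplotlib 3.10.9 under Python 3.11.15.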

Results

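The testis transcriptome was measured on 12 arrays, 3 for each combination of a casein or soy protein isolate diet with or without infused estradiol. Casein is a milk protein free of isoflavones, and soy protein isolate carries isoflavones, plant compounds that bind estrogen receptors. The animals were at an age when meiosis is under way and the first spermatids are forming. Arrays of 1 group correlated at 0.988 to 0.997, and the array medians lay between 6.72 and 6.79 log2. Gene values below are log2 means ± SD with n = 3 arrays, and differences are on the log2 scale. Background was not measured. A group mean below 5.69, the level of the filter on low values, was treated as possibly near background, and a difference from it as at most a lower bound.

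**Figure D1:**
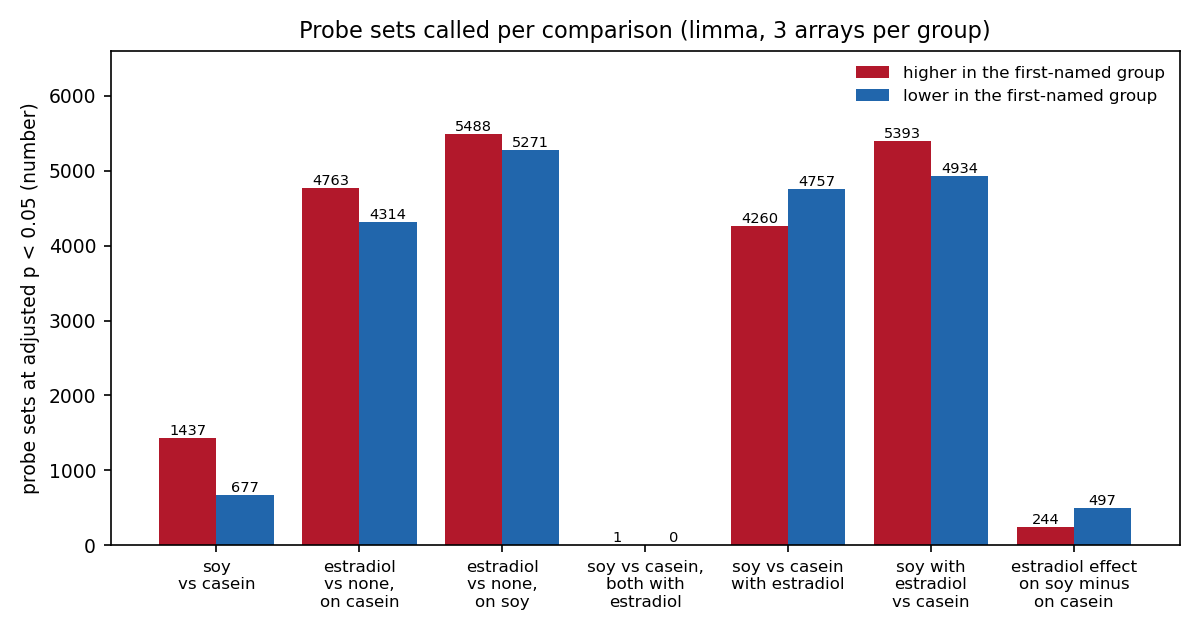
The bars give the number of probe sets called at an adjusted p under 0.05 (limma) in each of the 7 comparisons, split into those higher and those lower in the first-named group. Estradiol called 9077 probe sets on casein and 10759 on soy, the soy diet alone 2114, and the soy diet under estradiol 1.

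The comparison of estradiol with no estradiol on the casein diet asked how an exogenous estrogen altered the prepubertal testis. Of 10 measured Leydig cell markers 4 fell and 1 rose. Insl3, the Leydig cell hormone of testicular descent, went from 12.33 ± 0.06 to 10.72 ± 0.18 (n = 3), a 3.06-fold decrease (adjusted p = 2.01e-06). Hsd17b3, which converts androstenedione to testosterone, fell by 1.20 (adjusted p = 5.86e-06), while Hsd3b1, which makes progesterone from pregnenolone, rose from 11.44 ± 0.09 to 12.31 ± 0.26 (adjusted p = 0.000737). Most listed Sertoli cell markers rose and all measured spermatid markers fell in the same arrays.

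Other genes of steroid synthesis fell or were not called. Star, which carries cholesterol into mitochondria, fell by 0.47 on the probe set with the highest mean (adjusted p = 0.0418) and by 1.13 on another. Cyp11a1, which cleaves the cholesterol side chain, fell by 0.52 (adjusted p = 0.0250), and Hsd11b1, which interconverts active and inactive glucocorticoids, fell from 10.01 ± 0.18 to 8.51 ± 0.06 (adjusted p = 0.000129). The first Star call was lost without casein replicates 2 or 3 (adjusted p = 0.128 and 0.140) or casein with estradiol replicates 1, 2 or 3 (adjusted p = 0.0957, 0.110 and 0.0561). That of Cyp11a1 was lost without casein replicates 1 or 3 (adjusted p = 0.0877 and 0.0783) or casein with estradiol replicates 1 or 2 (adjusted p = 0.0522 and 0.102). Cyp17a1, which makes androgen precursors, differed by −0.28 and was not called (adjusted p = 0.215), nor was the luteinizing hormone receptor Lhcgr, with a difference of 0.04 (adjusted p = 0.764). Of 14 measured steroidogenesis genes 1 rose and 6 fell, the same numbers when adjusted over the list alone. The list did not pass camera, which sets it against all other genes, many of which also moved (adjusted p = 0.115). The Leydig cell markers also gave the same numbers over the list alone, 1 and 4 (camera adjusted p = 0.371). Of 18 cholesterol biosynthesis genes 1 rose and 5 fell over all probe sets and over the list alone, among them Fdps by 0.48 and Tm7sf2 by 0.45 (camera adjusted p = 0.247).

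Of 14 measured Sertoli cell markers 10 rose and 1 fell, or 12 and 1 when adjusted over the list alone, with a median difference of 0.67 (camera adjusted p = 9.53e-05). The call was lost with the estimated correlation, at an adjusted p = 0.641 with an estimated correlation. With fry the adjusted p was 0.00142 for this list and 0.00900 for spermatid markers. Cathepsin L (Ctsl), a protease released by Sertoli cells, rose from 10.53 ± 0.02 to 12.01 ± 0.20, and Testin, a Sertoli cell protein related to it, rose by 1.90 (adjusted p = 2.04e-05 for both). The tight junction gene Cldn11 rose by 0.86 and the cystatin gene Cst12 by 0.70. Inhbb, a subunit of inhibin and activin, rose by 0.34 (adjusted p = 0.00755), while Inha at 0.37 (adjusted p = 0.0559) and Amh at 0.26 (adjusted p = 0.0716) were not called. The 1 marker that fell was Rhox5, an androgen-induced homeobox gene, by 0.29. Its call was lost with the deposited values (adjusted p = 0.0561), without casein replicate 3 (adjusted p = 0.0801) and without casein with estradiol replicates 1 or 2 (adjusted p = 0.0629 and 0.0816).

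All 17 measured spermatid markers fell, also when adjusted over the list alone, with a median of −0.69 (camera adjusted p = 1.18e-05, and adjusted p = 0.641 with an estimated correlation). Prm2, a protamine that packs sperm DNA, fell from 12.03 ± 0.16 to 10.45 ± 0.67 (adjusted p = 0.00135), and the transition protein gene Tnp2 fell from 13.92 ± 0.05 to 12.82 ± 0.46 (adjusted p = 0.000882). Of 9 pachytene spermatocyte markers 0 rose and 3 fell over all probe sets and over the list alone (camera adjusted p = 0.115), including Calr3, a testis calreticulin, by 0.82, and the meiotic cyclin Ccna1 by 0.55. Early meiotic genes went the other way. In that list 5 of 7 rose, the same number adjusted over the list alone, with a median of 0.42 (camera adjusted p = 0.00299, and adjusted p = 0.589 with an estimated correlation). They included Sycp1, which rose by 0.63, and Sycp2, which rose by 0.57, both components of the synaptonemal complex. Among 11 spermatogonia markers 5 rose and 3 fell, or 6 and 3 over the list alone (camera adjusted p = 0.584). The cyclin gene Ccnd2 rose by 1.29, while Gfra1 fell by 0.81 and Ret by 0.57, the receptor subunits for the Sertoli cell factor Gdnf.

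Of 13 macrophage and leukocyte markers 0 rose and 8 fell, or 9 over the list alone, with a median of −0.35 (camera adjusted p = 0.0149, and adjusted p = 0.641 with an estimated correlation). Adgre1, a macrophage surface receptor, fell by 1.53 (adjusted p = 0.00156), Aif1, a calcium-binding protein, fell by 0.84 (adjusted p = 0.00499), and Tyrobp, a signalling adaptor of myeloid cells, fell by 0.49 (adjusted p = 0.00403). A second Aif1 probe set differed by −0.09 and was not called. Adgre1 and the first Aif1 probe set were lowest in casein with estradiol replicate 3 (6.10 and 10.46) and soy with estradiol replicate 1 (6.23 and 11.02). These arrays also had the lowest spermatid scores, a match seen only after the data were examined, so these falls were not assigned to macrophages. The large changes outside these lists included Ces1d, a carboxylesterase, which fell from 11.18 ± 0.13 to 8.65 ± 0.39 (adjusted p = 4.12e-05), and the troponin gene Tnnc1, which fell by 2.01. Sf3b1, a splicing factor, rose by 2.40, the tRNA synthetase gene Eprs1 by 2.35 and the ubiquitin ligase gene Huwe1 by 2.31, on probe sets that were low in the casein arrays alone. The casein means of Sf3b1 (5.45) and Huwe1 (5.39) lay below the filter level, so these differences are at most lower bounds. Other probe sets of Eprs1 and Huwe1 moved less. Those of Eprs1 read 9.78 to 9.83 and 9.95 to 10.07 in casein, against 9.91 to 10.07 and 10.36 to 10.64 in casein with estradiol. Those of Huwe1 read 9.08 to 9.28 and 6.10 to 6.27, against 9.68 to 9.81 and 6.59 to 6.79. Car3, a carbonic anhydrase abundant in muscle and fat, rose by 3.11 (adjusted p = 0.0229), a call lost without casein with estradiol replicate 2, where its difference was 2.37 (adjusted p = 0.0878). It was also lost without casein replicates 1 and 2 and casein with estradiol replicate 1 (adjusted p = 0.0592, 0.0640 and 0.0552), and without both casein with estradiol replicate 2 and soy with estradiol replicate 1 (adjusted p = 0.0803), left out together after their foreign transcripts were seen.

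In all, limma called 9077 of 21729 probe sets, 4763 higher and 4314 lower, of which 138 rose and 298 fell more than 2-fold. The share of rises among calls was 52.5%, and 40.9% with arrays centred on their medians. The call of the macrophage list was also lost with a 50% filter (adjusted p = 0.0618).

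**Figure D2:**
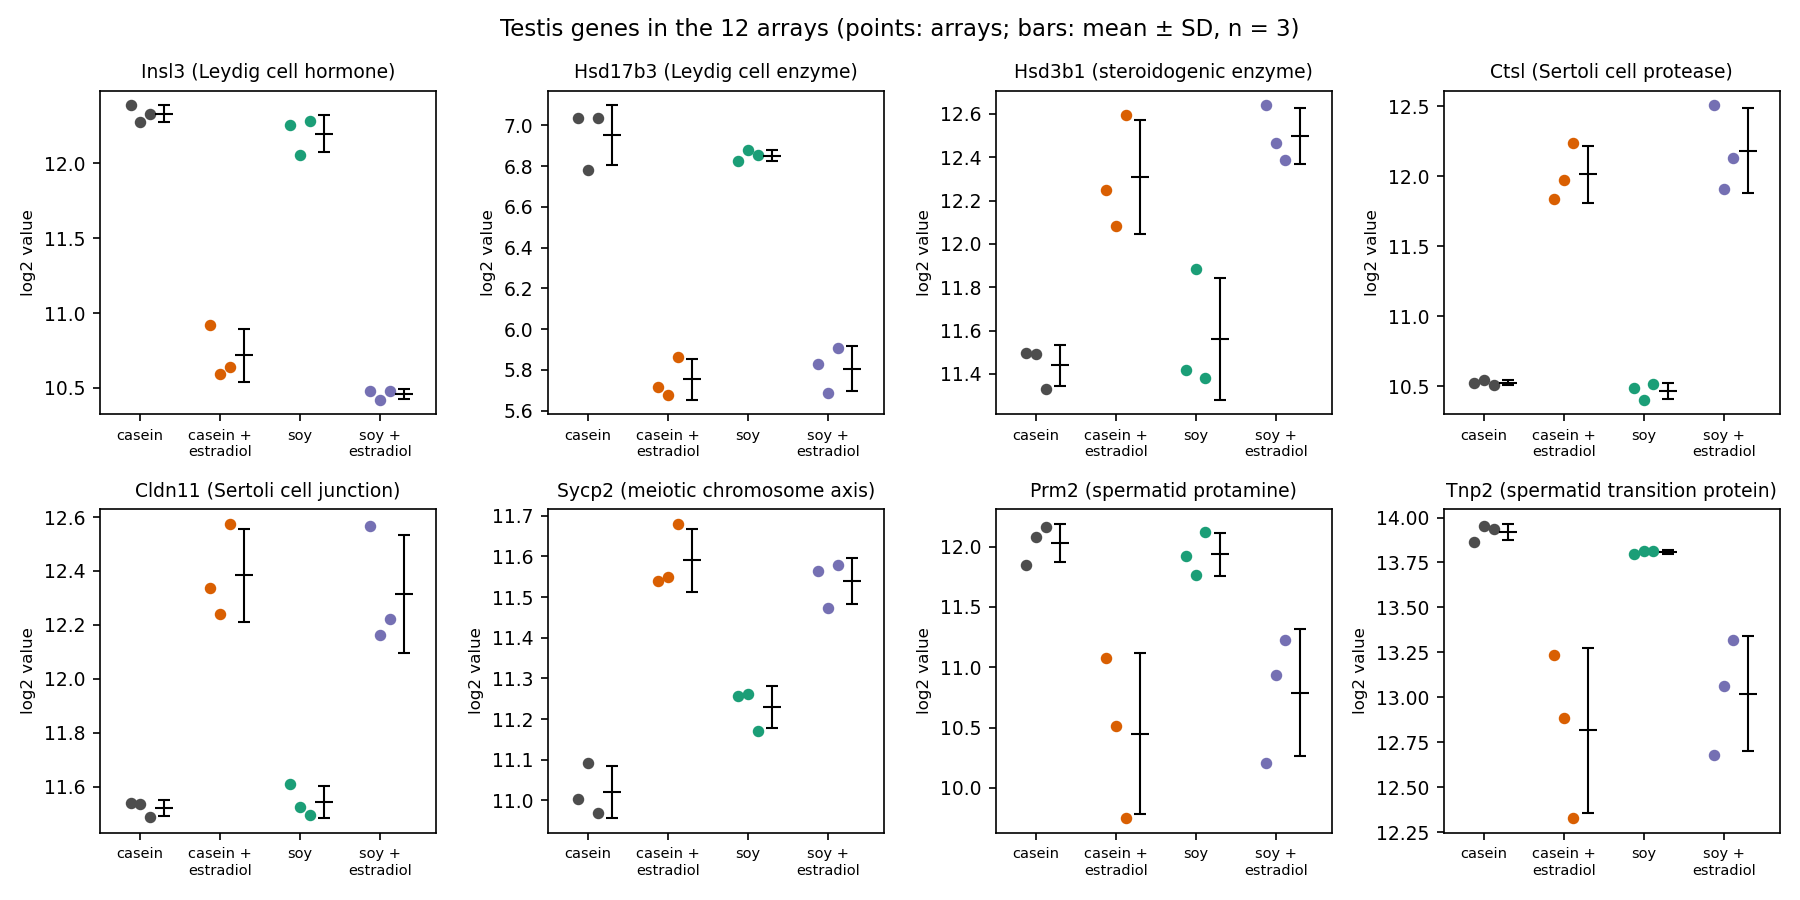
Each panel gives the log2 value of 1 gene in the 12 arrays by group, with points for arrays and bars for the mean ± SD (n = 3). Insl3 averaged 12.33 in casein and 12.20 in soy against 10.72 and 10.46 with estradiol, and Ctsl averaged 10.53 in casein against 12.01 in casein with estradiol.

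Estradiol on the soy diet gave a second measurement of the estradiol effect, on arrays that the first did not use. Insl3 fell by 1.74, from 12.20 ± 0.12 to 10.46 ± 0.03 (adjusted p = 1.07e-06), and Hsd17b3 fell by 1.05 (adjusted p = 2.79e-05). Most listed Sertoli cell markers rose again, among them Ctsl by 1.71 (adjusted p = 1.71e-05), and Testin rose by 2.34 (adjusted p = 1.03e-05). Most listed pachytene spermatocyte and spermatid markers fell, and Ces1d fell by 3.33, a 10.05-fold decrease (adjusted p = 1.68e-05).

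In the steroid pathway Star fell by 0.54 (adjusted p = 0.0193) and by 0.85 on another probe set, Cyp11a1 by 0.63 (adjusted p = 0.00873), Cyp17a1 by 0.57 (adjusted p = 0.0172) and Hsd11b1 by 1.28. Hsd3b1 rose by 0.94 (adjusted p = 0.000377). The first Star call was lost with the deposited values (adjusted p = 0.0604), with arrays centred on medians (0.0513), and without soy replicate 2 (0.0705) or soy with estradiol replicates 2 or 3 (0.0631 and 0.0738). That of Cyp17a1 was lost without soy replicate 2 or soy with estradiol replicate 2 (adjusted p = 0.0707 and 0.0570). Of 14 steroidogenesis genes 2 rose and 6 fell over all probe sets and over the list alone (camera adjusted p = 0.430), and of 10 Leydig cell markers 3 rose and 5 fell by both counts (camera adjusted p = 0.716). Of 18 cholesterol biosynthesis genes 1 rose and 6 fell by both counts, and the mevalonate pathway gene Mvd fell by 0.44 (camera adjusted p = 0.126). Of 14 Sertoli cell markers 10 rose and 0 fell by both counts, with a median of 0.63 (camera adjusted p = 0.000224, and adjusted p = 0.630 with an estimated correlation). Cst12 rose by 0.95, Kitlg, the ligand of the Kit receptor on spermatogonia, by 0.86, Amh, the anti-Müllerian hormone, by 0.69 (adjusted p = 0.000388) and Inhbb by 0.57.

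Of 17 spermatid markers 15 fell and 0 rose by both counts, with a median of −0.50 (camera adjusted p = 0.000388, and adjusted p = 0.630 with an estimated correlation). Acr, the protease of the acrosome, fell by 0.94 (adjusted p = 0.000572), Akap4, a scaffold of the sperm tail, by 0.89 (adjusted p = 0.00295), and the tail fibre gene Odf2 by 0.43. Of 9 pachytene markers 6 fell, or 7 over the list alone, with a median of −0.47 (camera adjusted p = 0.00523, and adjusted p = 0.630 with an estimated correlation). Calr3 fell by 0.81, Ccna1 by 0.75 and Tcp11 by 0.57. Of 7 early meiotic markers 5 rose by both counts, including Tex15, needed for male meiosis, by 0.51, and the list did not pass camera (adjusted p = 0.0858). Of 13 macrophage and leukocyte markers 1 rose and 2 fell, or 1 and 1 over the list alone, with a median of −0.02 (camera adjusted p = 0.959). Cd74, the invariant chain of antigen presentation, rose by 1.16 and Adgre1 fell by 0.99, a call lost without soy with estradiol replicate 1 (adjusted p = 0.0501).

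Among estrogen-linked genes Greb1, which estrogen induces in reproductive tissues, rose from 5.95 ± 0.10 to 6.95 ± 0.16 on soy (adjusted p = 6.10e-05), and on casein its difference was 0.23 (adjusted p = 0.0800). The test of that difference between diets gave 0.77 (adjusted p = 0.0159), a call lost without casein replicate 3 (adjusted p = 0.0508) or casein with estradiol replicate 1 (adjusted p = 0.0504). Another Greb1 probe set differed by −0.14 on soy and was not called. Trh, which encodes thyrotropin-releasing hormone, fell by 0.60 on soy and by 0.84 on casein. Of the 6 measured classical estrogen receptor targets 2 rose and 1 fell on soy and 1 rose and 1 fell on casein, each the same over the list alone (camera adjusted p = 0.893 and 0.978). The estrogen-metabolising enzyme gene Cyp1b1 fell by 0.86 and the glucocorticoid receptor Nr3c1 rose by 0.64 on soy. Ass1, which makes argininosuccinate in arginine synthesis, fell by 1.93 (adjusted p = 9.08e-05) and Tnnc1 by 1.82. Myh6, a cardiac myosin heavy chain, rose from 6.16 ± 0.16 to 8.49 ± 0.08 (adjusted p = 1.01e-06), and Nxpe2 rose by 1.78.

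On soy, limma called 10759 probe sets, 5488 higher and 5271 lower, of which 93 rose and 168 fell more than 2-fold. Across genes the estradiol effects on the diets correlated at r = 0.743 (rho = 0.724). They shared 3212 rises (1203 expected by chance) and 2916 falls (1046 expected), with 157 calls in opposite directions (2245 expected).

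**Figure D3:**
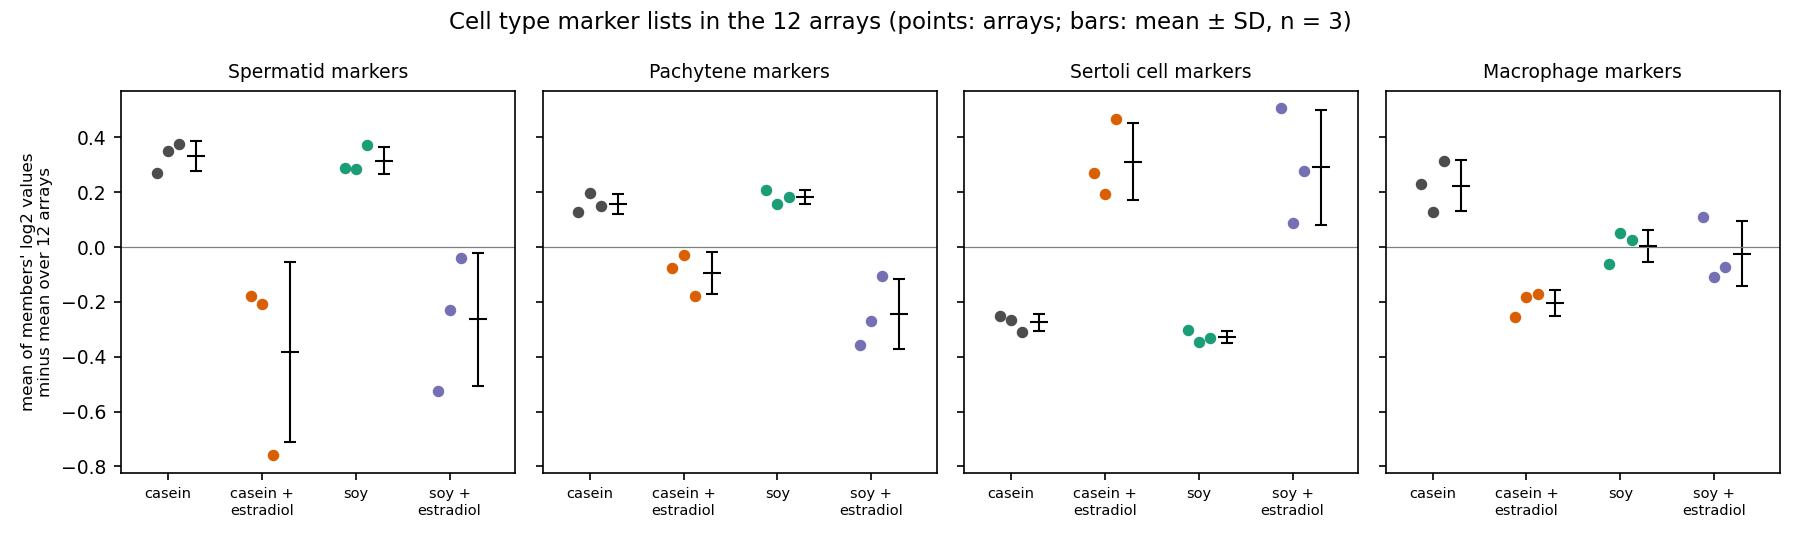
Points give, for each of the 12 arrays by group, the mean of a list's log2 values minus its mean over the 12 arrays, with bars for the mean ± SD (n = 3). Spermatid scores lay between 0.27 and 0.37 in the 6 arrays without estradiol and between −0.76 and −0.04 in the 6 with it, and Sertoli cell scores between −0.35 and −0.25 and between 0.09 and 0.51.

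The comparison of soy with casein, without estradiol, addressed the effect of the soy diet itself. The Leydig and Sertoli cell markers were not called. Insl3 differed by −0.13 (adjusted p = 0.415), Star by 0.11 (adjusted p = 0.762), Hsd3b1 by 0.12 (adjusted p = 0.671), Amh by −0.24 (adjusted p = 0.184) and Inhbb by −0.20 (adjusted p = 0.177). The genes that rose most were Eprs1, Huwe1 and the membrane protein gene Tm9sf3, and they also included Pbrm1, a subunit of a chromatin remodeller. The inflammatory protease gene Casp1 was among those that fell.

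Eprs1 rose from 7.10 ± 0.05 to 9.34 ± 0.16 (adjusted p = 6.28e-06), and its other probe sets differed by −0.09 (adjusted p = 0.703) and 0.18 (adjusted p = 0.189). Huwe1 rose by 1.97 (SE 0.17) on 1 probe set, with 0.26 and −0.01 on others that were not called. The spindle checkpoint kinase gene Ttk rose by 1.70, against 0.29 on its other probe set (adjusted p = 0.0521). Further rises were Tm9sf3 by 1.88, Ralgapa1 by 1.87, Pbrm1 by 1.67, Gpbp1 by 1.65, the deubiquitinase gene Usp8 by 1.61, Sf3b1 by 1.57 and Prrc2c by 1.54. The casein means of Huwe1, Sf3b1 and Ralgapa1 lay below the filter level, so these rises are at most lower bounds. Hivep1, a zinc finger transcription factor, fell from 7.18 ± 0.08 to 6.37 ± 0.28 (adjusted p = 0.00322), and Casp1 fell from 6.44 ± 0.11 to 5.73 ± 0.11 (adjusted p = 0.00192). The calcium channel gene Orai2 fell by 0.69, the kinase gene Nlk by 0.68, and Ipp and Osbpl3 by 0.65 each. Mospd2 fell by 0.70, a call lost when any of casein replicates 1, 2 and 3 or soy replicates 1 and 3 was left out (adjusted p = 0.101, 0.0618, 0.116, 0.0918 and 0.14998).

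None of the 25 lists passed camera on soy, with the preset or the estimated correlation. Of 13 macrophage markers 1 fell over all probe sets and over the list alone, Tyrobp by 0.42, with a list median of −0.27 (camera adjusted p = 0.166). The Tyrobp call was lost without casein replicates 1 or 3 (adjusted p = 0.0693 and 0.129) or soy replicates 1 or 3 (adjusted p = 0.105 and 0.110). Of 7 early meiotic markers 1 rose, or 2 over the list alone: Smc1b, a cohesin of meiotic chromosomes, by 0.38 (camera adjusted p = 0.166), a call lost with arrays centred on medians (adjusted p = 0.0516) or without soy replicate 1 (adjusted p = 0.0503). All 14 Sertoli, 17 spermatid and 10 Leydig cell markers were not called over all probe sets or over the list alone (camera adjusted p = 0.998 for each). The other list members that passed were the orphan nuclear receptor gene Nr2f2, which rose by 0.58 (adjusted p = 0.00193), Lipe, a lipase of fat cells, which rose by 0.44, Cyp1a2, which rose by 0.44 (adjusted p = 0.0140), and Mki67, which rose by 0.35 (adjusted p = 0.0174). Ret fell by 0.51 (adjusted p = 0.0149), Mcm4 by 0.41 (0.0176), Hspa1a by 0.36 (0.0245), Nr3c1 by 0.32 (0.0377), Stra6 by 0.31 (0.0484) and Greb1 by 0.37 (adjusted p = 0.0326). With 1 array left out the calls of Cyp1a2, Mki67, Ret, Mcm4, Hspa1a, Nr3c1 and Stra6 were lost, at adjusted p up to 0.0533, 0.0687, 0.0671, 0.0776, 0.0999, 0.148 and 0.185. That of Mki67 was also lost with the deposited values and with arrays centred on medians (adjusted p = 0.0612 and 0.0898), and that of Stra6 with a 50% filter and with none (0.0525 and 0.0553). The Greb1 call was lost with the deposited values (adjusted p = 0.0677), without casein replicates 1, 2 or 3 (adjusted p = 0.0564, 0.0848 and 0.111) and without soy replicates 1 or 3 (adjusted p = 0.101 and 0.123).

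The hybridisation controls, spiked transcripts that are not of rat, averaged 10.46 ± 0.07 in the casein arrays (n = 3), 10.88 ± 0.03 in soy, 10.79 ± 0.11 in casein with estradiol and 11.01 ± 0.05 in soy with estradiol. Eprs1, Huwe1 and Ttk were low in casein alone. For Eprs1 the means were 9.46 ± 0.13 in casein with estradiol and 9.74 ± 0.33 in soy with estradiol. In all, limma called 2114 probe sets, 1437 higher and 677 lower in soy, of which 66 rose and 0 fell more than 2-fold. The share of rises among calls was 68.0%, 49.5% of 3934 calls with the deposited values and 36.7% of 4566 with arrays centred on their medians, where the median of all probe sets shifted by −0.11. The soy arrays also stood apart, with narrower deposited values. Their lower quartiles were 5.41 to 5.47 and their upper quartiles 8.33 to 8.39, against 5.30 to 5.38 and 8.45 to 8.52 in the other 9 arrays. The count dropped to 1318 without casein replicate 2, 1000 without casein replicate 3, 1052 without soy replicate 1 and 1064 without soy replicate 3.

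**Figure D4:**
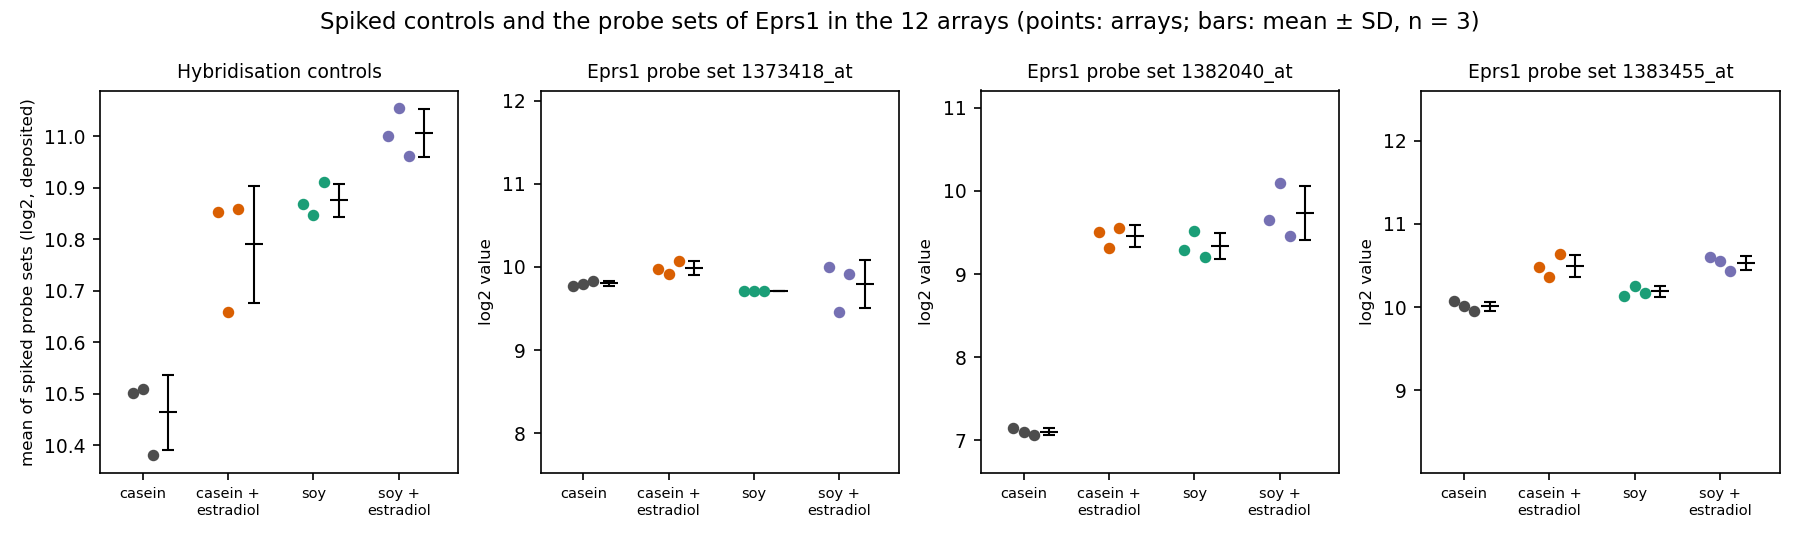
The panels give, for the 12 arrays by group, the mean log2 value of 9 spiked hybridisation probe sets and the log2 values of the Eprs1 probe sets, with points for arrays and bars for the mean ± SD (n = 3). The controls averaged 10.46 in casein and 10.88 in soy, and 1 Eprs1 probe set differed between these groups by 2.23 while the others differed by −0.09 and 0.18.

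The soy diet was also set directly against estradiol on casein, which asks whether soy acted as the hormone did. Insl3 was higher in soy than in casein with estradiol by 1.48 (adjusted p = 7.85e-06) and Hsd17b3 by 1.10 (adjusted p = 6.30e-05). Testin was lower, with a difference of −2.18 (adjusted p = 5.19e-05), and so was Ctsl, with −1.55 (adjusted p = 6.92e-05). All measured spermatid markers were higher and most listed Sertoli cell markers lower in soy.

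Sertoli cell markers had a camera adjusted p = 1.58e-05, spermatid markers 8.25e-06, and early meiotic markers, lower in soy, 0.0322, each with an adjusted p = 0.627 with an estimated correlation. Of 14 Sertoli cell markers 12 were lower and 1 was higher in soy, all 17 spermatid markers were higher, and 4 of 7 early meiotic markers were lower, with the same numbers adjusted over the list alone. Akap4 was higher by 1.03, Tnp2 by 0.99, Hsd11b1 by 1.27 and Ces1d by 2.34 (adjusted p = 0.000218 for Ces1d). Hsd3b1 differed by −0.75 (adjusted p = 0.00234), Greb1 by −0.59, Myh6 by −1.86, Nxpe2 by −1.51, and Rps6ka6 and Mcub by −1.19 each. Wfdc10a differed by −1.14 and Shbg, the androgen-binding protein of Sertoli cells, by −1.13 (adjusted p = 0.00216). Fos, an immediate early gene, differed by −1.17 (adjusted p = 0.0123), a call lost without casein with estradiol replicate 1 (adjusted p = 0.0513). The soy means of Nxpe2 (5.48), Rps6ka6 (5.52) and Fos (5.32) lay below the filter level, so these differences are at most lower bounds. In all, limma called 9017 probe sets, 4260 higher and 4757 lower in soy, and 5454 without casein with estradiol replicate 3. Of the 9017, 177 were higher and 37 lower by more than 2-fold. The share higher was 47.2%, 40.0% with the deposited values and 42.8% with arrays centred on medians. The call of the early meiotic spermatocyte list was also lost with the deposited values (adjusted p = 0.0801), arrays centred on medians (0.0967), a 50% filter (0.0549), without soy replicate 3 (0.0510), and without both arrays with foreign transcripts named above (0.0728).

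Across genes the effects of soy and of estradiol, each against the same casein arrays, correlated at r = 0.422 (rho = 0.341). Unchanged groups were simulated by shuffling the values of all arrays left after group means were removed. A simulated group took the place of casein in both effects. These simulations gave a mean r of 0.460 (lower and upper quantiles −0.187 and 0.828). The covariance was 0.0332 against 0.00807 in the simulation, a difference of 0.0251. Both effects called 854 probe sets higher (315 expected) and 277 lower (134 expected), and 71 in opposite directions (434 expected). The shared casein arrays raise the first 2 of these counts and lower the third. Eprs1, Huwe1 and Sf3b1 were among the largest rises of both.

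Under estradiol, soy was compared with casein to ask whether the diet mattered once the hormone was given. The steroid, Sertoli cell and germ cell genes named above were not called. Insl3 differed by −0.26 (adjusted p = 0.288) and Greb1 by 0.40 (adjusted p = 0.204). The smallest unadjusted p-values belonged to Serpinb9, a protease inhibitor, with a difference of 0.60, Mex3a with 0.55 and Plac8 with 0.55, and among lower values to Atp8a1 with −0.53, Efhd1 with −0.53 and Ankrd54 with −0.55, all at an adjusted p of 0.184.

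limma called 1 probe set at an adjusted p under 0.05, and 2784 had an unadjusted p under 0.05. The called probe set, 1382482_at, has no gene symbol and was chosen after its values were seen. It averaged 5.81 in casein with estradiol and 6.68 in soy with estradiol, a difference of 0.87 (adjusted p = 0.0245). Of 9 pachytene markers 0 were called over all probe sets and 3 fell when adjusted over the list alone, with a median of −0.10 (camera adjusted p = 0.0284, and adjusted p = 0.558 with an estimated correlation), and Tcp11 differed by −0.41 (adjusted p = 0.184). The call of the pachytene spermatocyte list was also lost with fry (adjusted p = 0.327), with arrays centred on medians (0.0592), without casein with estradiol replicate 2 (0.0821), without soy with estradiol replicate 1 (0.370), and without both of these arrays (0.646). The count of called probe sets was 0 without casein with estradiol replicates 1 or 3 or soy with estradiol replicates 1 or 2, 373 without soy with estradiol replicate 3, and 707 without both casein with estradiol replicate 2, which carried a muscle transcript, and soy with estradiol replicate 1, which carried epididymal ones, a choice made after the data were seen. The soy effects with and without estradiol correlated across genes at r = 0.0255 (rho = −0.0301).

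Both treatments were set against neither in the comparison of soy with estradiol with casein. Ces1d fell by 3.51, an 11.4-fold decrease (adjusted p = 3.08e-06), Insl3 fell by 1.87 (adjusted p = 4.83e-07) and the hemoglobin-binding gene Hp fell from 8.99 ± 0.17 to 7.10 ± 0.05 (adjusted p = 1.10e-06). Testin rose by 2.05 (adjusted p = 6.09e-06), Myh6 by 2.07 (adjusted p = 4.83e-07) and Eprs1 by 2.64 (adjusted p = 4.83e-07). Sf3b1 rose by 2.62, Huwe1 by 2.51 and Tm9sf3 by 2.11, at most lower bounds for Sf3b1 and Huwe1. The values of Eprs1 and Huwe1 come from 1 probe set each, and their other probe sets moved less. Those of Eprs1 read 9.78 to 9.83 and 9.95 to 10.07 in casein, against 9.46 to 10.00 and 10.44 to 10.60 in soy with estradiol. Those of Huwe1 read 9.08 to 9.28 and 6.10 to 6.27, against 9.49 to 9.87 and 6.56 to 6.97. The fatty acid transporter gene Cd36 fell by 1.64 (adjusted p = 8.90e-05).

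Of 14 Sertoli cell markers 9 rose by both counts, with a median of 0.46 (camera adjusted p = 0.000347). Of 17 spermatid markers 15 fell by both counts, with a median of −0.52 (camera adjusted p = 0.000347). Of 7 early meiotic markers 5 rose by both counts, and of 9 pachytene markers 6 fell, or 7 over the list alone (camera adjusted p = 0.00930 for both). Each of these 4 lists had an adjusted p = 0.696 with an estimated correlation. The call of the early meiotic spermatocyte list was also lost with the deposited values (adjusted p = 0.0681) and with arrays centred on medians (0.0738). Car3 rose by 3.91 (adjusted p = 0.00599). Fabp4, a fatty acid carrier of fat cells, rose by 2.20 (adjusted p = 0.0360), a call lost without casein replicates 1 or 2 or soy with estradiol replicates 1 or 3 (adjusted p = 0.101, 0.0890, 0.0579 and 0.140). The casein means of Car3 (5.23) and Fabp4 (4.86) also lay below the filter level. Further falls were Tnnc1 by 1.94, Ass1 by 1.86, Fscn3, an actin bundler of the testis, by 1.72, the histocompatibility gene RT1-CE5 by 1.70 and Sec22a by 1.68. In all, limma called 10327 probe sets, 5393 higher and 4934 lower, of which 236 rose and 299 fell more than 2-fold. The share of rises was 52.2%, and 42.7% with arrays centred on their medians.

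The interaction tested whether the estradiol effect differed between diets. Testicular hormone genes passed no such test, with Insl3 at −0.13 (adjusted p = 0.591). The estradiol effect was less positive on soy for the probe sets that were low in casein alone, with Ralgapa1 at −2.37 (adjusted p = 0.00467), Eprs1 at −1.95 (adjusted p = 0.000749), Huwe1 at −1.77 (adjusted p = 0.00550) and Tm9sf3 at −1.68. For Ralgapa1 and Huwe1 these rest on casein means below the filter level. It was more positive on soy for the membrane gene Tspan8 at 1.10, Gtf2e1, a general transcription factor, at 0.92 (adjusted p = 0.00961), and the kinase gene Nlk at 0.92, where the soy mean of Gtf2e1 (5.17) lay below the filter level. Macrophage markers were more positive on soy as a list, with a median of 0.39 (camera adjusted p = 0.00820, and adjusted p = 0.882 with an estimated correlation). The call was also lost with fry (adjusted p = 0.182).

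Of 13 macrophage markers 1 was called, Tyrobp at 0.62 (adjusted p = 0.0493), and 2 passed adjusted over the list alone. The call of the macrophage list was lost with the deposited values (adjusted p = 0.0792), arrays centred on medians (0.0939), a 50% filter (0.106), without soy with estradiol replicate 1 (0.0969), and without both that array and casein with estradiol replicate 2 (0.117). The Tyrobp call was lost with the deposited values (adjusted p = 0.0574) and without a filter (0.0589). It was also lost without casein replicates 1, 2 or 3 (0.0767, 0.0520 and 0.116), casein with estradiol replicates 1, 2 or 3 (0.121, 0.0731 and 0.0928), soy replicates 1 or 3 (0.117 and 0.106) or soy with estradiol replicates 1 or 2 (0.0576 and 0.0753). In all, limma called 741 probe sets, 244 more positive and 497 less positive on soy. Rises were 32.9% of calls, 45.0% with the deposited values and 58.9% with arrays centred on their medians. Of the 497, 471 (94.8%) were also called higher in soy than in casein, and of the 244, 185 (75.8%) were also called lower. The interaction holds the difference of soy and casein with its sign turned, so such overlap is built in and has no chance value here. The count fell to 467, 277 and 157 without casein replicates 1, 2 and 3, to 156, 281 and 263 without casein with estradiol replicates 1, 2 and 3, and to 173 and 284 without soy replicates 1 and 3. The Nlk call was lost without casein replicate 3 or casein with estradiol replicate 1 (adjusted p = 0.0508 and 0.0504). The Tspan8 call was lost without casein replicates 1, 2 or 3 (adjusted p = 0.0669, 0.0628 and 0.0809), casein with estradiol replicates 1 or 3 (0.0934 and 0.0764), soy replicates 1 or 3 (0.0910 and 0.0804) or soy with estradiol replicates 1 or 3 (0.0510 and 0.0511).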

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

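The tests of the first 3 paragraphs and the 20 interaction splits in the last were chosen only after the results were seen, while the other counts over splits of the arrays had been planned. The hybridisation controls differed between groups in data outside the comparisons. These spiked transcripts, not of rat, averaged 0.426 log2 higher in the other 9 arrays than in the 3 casein arrays (exact permutation p = 0.00455, adjusted p = 0.0795 over 35 tests). All 3 casein arrays lay below the other 9. Casein was not the only group apart. The soy with estradiol arrays read 10.96 to 11.05, above the highest other array, soy replicate 3 at 10.91. Under estradiol the controls were 0.215 higher in soy than in casein (exact permutation p = 0.1, the smallest that 3 against 3 can give, adjusted p = 0.206). In that comparison limma called 1 probe set. The probe sets called higher in soy than in casein, such as those of Eprs1, Huwe1 and Ttk, were low in the casein arrays. For 647 of these called probe sets, other probe sets of the same gene were tested. Those changed by a median of only 0.0885 of the called one (95% interval 0.0560 to 0.115). Probe sets called higher for estradiol on soy gave 0.441 (0.386 to 0.483). Both intervals came from resampling genes and leave out the variation between arrays. Within these arrays, the ratios argue against a rise of the whole gene's mRNA. The low controls in casein leave open that the casein arrays were hybridised apart. That split is the same as the diet group without hormone and cannot be told apart from it. The control differences between other groups limit this reading. Greater degradation of the casein RNA could not be settled because the hexokinase 3′ over 5′ ratio differed by −0.395 (exact permutation p = 0.00909, adjusted p = 0.106) but those of actin and GAPDH by 0.036 and 0.0006. An effect of the diet on transcript ends or isoforms stays open as untested.

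Car3, Fabp4 and Lpl varied between arrays of 1 group and had their lowest group means in casein, and Car3's call for estradiol on casein and Fabp4's for both treatments with neither were lost when 1 array was left out. Car3 and Fabp4 moved together after group means were removed, with r = 0.938 (permutation p = 0.0034, adjusted p = 0.0074 over 6 relations), and across all 12 arrays r was 0.940 and rho 0.958 (permutation p = 4e-05 and 2e-05, adjusted p = 8e-05), or 0.941 without the 2 arrays farthest from the median. Within groups Car3 also followed Lpl (r = 0.968), Adipoq (0.946) and Cfd (0.887), but not Lipe (−0.369) or Cidec (0.493, permutation p = 0.167). A candidate explanation is fat carried over with the testis, in amounts that differed between samples. A change of fat metabolism within the testis with diet or hormone remains open as untested.

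Under estradiol most listed spermatid markers fell and most listed Sertoli cell markers rose on each diet. Both list calls of camera were lost with the estimated correlation (adjusted p = 0.641 on casein and 0.630 on soy). A lower share of spermatids alone would raise the markers of all other cell types alike, yet under estradiol the Sertoli cell list gained 0.810 log2 over the endothelial list (mean of both diets; exact permutation p = 0.005, the smallest that 400 splits can give, adjusted p = 0.005 over 8 tests). The list medians kept at least 0.826 of their size in the deposited values, which argues against the added quantile normalization as their source. Any earlier normalization of the deposited values is not known, so an effect of it could not be tested. A change within Sertoli cells or in their share may therefore accompany the spermatid change, a hypothesis found and tested on the same arrays. Direct action of estradiol on the testis and loss of pituitary stimulation remain open as untested.

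For the interaction, the test of whether the estradiol effect differed between diets, limma called 741 probe sets. With 1 array left out the count ran from 156 to 1049, and other splits of the estradiol arrays gave up to 1527. The count is therefore no measure of how many probe sets responded differently by diet. Among named genes the difference was 1.10 for Tspan8, 0.92 for Gtf2e1, 0.92 for Nlk, 0.83 for Plcl1, 0.83 for Tcf7, 0.83 for Tsr2, 0.82 for Ssh3, 0.81 for Clec4a3, 0.79 for Slc31a2 and 0.79 for Snhg4, and all of these calls except those of Gtf2e1 and Tsr2 were lost in at least 1 alternative. The soy means of Gtf2e1 (5.17) and Slc31a2 (5.37) lay below the level of the filter, as did the casein means of Ralgapa1 and Huwe1. In the other direction it was −2.37 for Ralgapa1, −1.95 for Eprs1, −1.77 for Huwe1, −1.68 for Tm9sf3, −1.65 for Lrpprc, −1.60 for Usp8, −1.58 for Pbrm1, −1.52 for Gpbp1, −1.48 for Ttk and −1.46 for Usp42, all on probe sets with their lowest group mean in casein, the arrays with the lowest hybridisation controls. The macrophage and leukocyte list had a median difference of 0.39, with an adjusted p = 0.882 with an estimated correlation. Its call was also lost with the deposited values (adjusted p = 0.0792), with arrays centred on medians (0.0939), with a 50% filter (0.106), without soy with estradiol replicate 1 (0.0969), without both that array and casein with estradiol replicate 2 (0.117), and with fry (0.182).

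Other splits of the same arrays were counted for each comparison. For the interaction, 1 of 100 random splits of the 12 arrays gave as many calls, the real one with 741, and the highest of the others gave 32. Those splits mix arrays with and without estradiol, which widens the spread within groups, so they say nothing on chance. With the arrays without estradiol kept in their groups, 5 of 20 splits of the 6 estradiol arrays gave as many, the highest other with 1527. All 20 keep the difference of soy and casein without estradiol inside the interaction. Calls in them, at least 175, are thus built in and do not gauge chance. In addition, 20 splits are too few for a share under 0.05. The 10 splits of 6 arrays are too few as well. Every split other than the real one puts arrays of both groups on each side. A real difference then widens the spread within groups and lowers the calls, so low counts in those splits do not gauge chance. The real and highest other counts were 2114 and 1 for soy with casein, 9077 and 0 for estradiol on casein, 10759 and 0 for estradiol on soy, 9017 and 0 for soy with estradiol on casein, and 10327 and 0 for both treatments with neither, with 1 split of 10 reaching the real count in each. For soy with casein under estradiol 3 of 10 splits gave as many, the real count being 1 and the highest other 1193. That split set casein with estradiol replicates 1 and 3 and soy with estradiol replicate 1 against casein with estradiol replicate 2 and soy with estradiol replicates 2 and 3, and another gave 135, which points to a structure among the estradiol samples other than diet.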

How the results depend on the processing

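The alternative that left out casein with estradiol replicate 2 and soy with estradiol replicate 1 together, as arrays with transcripts of neighbouring tissues, was chosen only after the data were seen. It kept casein replicate 1 and soy replicate 2, which also carried epididymal transcripts and were each left out on their own. Values were already on the log2 scale, so the offsets planned for linear values were not run. The filter on low values limited the tests to probe sets with means above 5.69 log2. Of the 120 calls among the largest rises and falls of the 7 comparisons 0 reversed in any alternative run for them and 12 were lost in at least 1, namely Car3, Fabp4, Fos, Mospd2 and, for the interaction, Clec4a3, Nlk, Plcl1, Slc31a2, Snhg4, Ssh3, Tcf7 and Tspan8. Of 277 calls of other named genes 0 reversed and 71 were lost in at least 1. Where a value below moved, the cause was not tested, except that 1 probe set per gene, fewer arrays and a fold limit leave fewer probe sets or less precision by construction.

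With 1 probe set per gene the calls were 629 for soy with casein, 5259 for estradiol on casein, 6118 for estradiol on soy, 0 for soy with casein under estradiol, 5320 for soy with estradiol on casein, 5777 for both treatments with neither and 91 for the interaction. With a fold over 1.5 and an unadjusted p under 0.05, which controls no error rate, they were 309, 2242, 2538, 173, 1811 and 2929 in the same order without the interaction. Soy with casein gave 4566 calls with arrays centred on medians, 3934 with the deposited values, 3414 with its own groups only and 1236 with a 50% filter. The interaction gave 1244 with arrays centred on medians, 434 with a 50% filter and 393 with the replicate number as a block. For soy with casein under estradiol, limma gave 0 with its own groups only, with a 50% filter and with the block, and 707 without the arrays with foreign transcripts. The replicate numbers did not pair the arrays: 4 of 18 pairs with the same number correlated above 0.1 (range −0.361 to 0.352), and 3 of 12 arrays correlated best with their own number. The block ended 14 calls of named genes and added 1, and for the interaction those of Tspan8, Tcf7, Ssh3 and Snhg4 were among the 14 (adjusted p = 0.0574, 0.0528, 0.0547 and 0.0592).

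Leaving out 1 array gave 6222 to 8434 calls for estradiol on casein, 8308 to 11266 for estradiol on soy and 8491 to 10811 for both treatments with neither. For soy with estradiol on casein it gave 5454, without casein with estradiol replicate 3, to 8472. For soy with casein it gave 1000 to 1881, with 1318 and 1000 without casein replicates 2 and 3 and 1052 and 1064 without soy replicates 1 and 3. For soy with casein under estradiol it gave 0 to 373, with 0 without casein with estradiol replicates 1 or 3 or soy with estradiol replicates 1 or 2, and 373 without soy with estradiol replicate 3. For the interaction it gave 156 to 1049, with 467, 277 and 157 without casein replicates 1, 2 and 3, 156, 281 and 263 without casein with estradiol replicates 1, 2 and 3, and 173 and 284 without soy replicates 1 and 3.

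With the estimated correlation 0 lists passed camera in any of the 7 comparisons. The mean over a gene's probe sets gave 5 lists for estradiol on soy in place of 3, and soy with casein gave 2 without a filter in place of 0. The interaction list was lost (0 lists) with arrays centred on medians, with the deposited values and with a 50% filter, and the list for soy with casein under estradiol was lost (0) with arrays centred on medians. Leaving out 1 array gave 4 to 5 lists for estradiol on casein, 3 to 4 on soy, 2 to 4 for soy with estradiol on casein and 4 to 6 for both treatments with neither. It gave 0 to 1 for soy with casein, with 1 without casein replicate 2. It gave 1 to 3 for soy with casein under estradiol, with 2 without casein with estradiol replicates 1 or 3 and 3 without casein with estradiol replicate 2 or soy with estradiol replicate 2. It gave 0 to 2 for the interaction, with 0 without soy with estradiol replicate 1 and 2 without casein with estradiol replicates 2 or 3, soy replicate 2 or soy with estradiol replicate 3. With fry, 14 of 25 lists passed for estradiol on casein and 13 on soy, where camera passed 4 and 3. fry passed 14 for soy with estradiol on casein and 13 for both treatments with neither. It passed 1 for soy with casein under estradiol, and 0 for soy with casein and for the interaction.

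Across genes, the estradiol effects on the diets correlated at 0.786 with a 50% filter, 0.709 with no filter, 0.657 without the arrays with foreign transcripts and 0.672 to 0.772 with 1 array left out. The soy and estradiol effects correlated at 0.469 with arrays centred on medians and with the deposited values, and at 0.358 to 0.480 with 1 array left out. The soy effects with and without estradiol correlated at 0.0598 with a 50% filter and at −0.0381 to 0.0839 with 1 array left out. The sign turned without casein replicate 1 (−0.0381), soy replicate 3 (−0.0101) and soy with estradiol replicate 2 (−0.0101), and the value was 0.0839 without casein replicate 3 and 0.0712 without soy replicate 1. All of these lie well inside the lower and upper quantiles, −0.653 and 0.592, of groups simulated as unchanged.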

Other observations

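The values per array and the relation between list scores, in the first and last paragraphs, were chosen only after the data were seen, while the list tests and members followed rules fixed in advance. The samples given estradiol differed among themselves in spermatid genes. The spermatid list score, the mean of its members minus their mean over 12 arrays, was −0.18, −0.21 and −0.76 in casein with estradiol replicates 1, 2 and 3 and −0.52, −0.23 and −0.04 in soy with estradiol replicates 1, 2 and 3, against 0.27 to 0.37 in the 6 arrays without estradiol. Prm2 and Tnp2 were lowest in casein with estradiol replicate 3, at 9.75 and 12.33, and in soy with estradiol replicate 1, at 10.21 and 12.68. Sertoli cell scores were 0.27, 0.19 and 0.47 in casein with estradiol and 0.51, 0.09 and 0.28 in soy with estradiol. Across these 6 arrays the spermatid and Sertoli cell scores correlated at r = −0.737 and rho = −0.371 (exact permutation p = 0.110 and 0.497 over 720 orders, adjusted p = 0.219 over 4 relations). Without the 2 arrays farthest from the median r was 0.712, so the relation rested on those arrays. It was not particular to Sertoli cells, as the spermatid score correlated with the Leydig cell score at r = −0.778 and rho = −0.543 (exact permutation p = 0.0722 and 0.297, adjusted p = 0.219), and at 0.488 without those 2 arrays. With the early meiotic and pachytene scores r was −0.592 and 0.478 and rho −0.429 and 0.6 (exact permutation p = 0.217 and 0.333 for r, adjusted p = 0.289 and 0.333).

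The heat shock, retinoid and mitotic lists did not pass camera for estradiol on either diet, and their members went both ways. Of 14 heat shock and unfolded protein genes 6 rose and 4 fell on casein, or 8 and 5 over the list alone (camera adjusted p = 0.735), and 4 rose and 3 fell on soy by both counts (camera adjusted p = 0.883). Hspb1, a small heat shock protein, fell by 1.11 on casein (adjusted p = 0.000144) and by 0.99 on soy, while Hsph1 rose by 0.63 on soy (adjusted p = 0.000417). Of 12 retinoid genes 5 rose and 2 fell on casein by both counts (camera adjusted p = 0.772), and 6 rose and 3 fell on soy, or 7 and 3 over the list alone (camera adjusted p = 0.307). Cyp26b1, which degrades retinoic acid, rose by 0.47 on casein and by 0.66 on soy, and Crabp1, which binds retinoic acid in cells, rose by 0.53 and 0.80. Rdh10, which makes retinal from retinol, fell by 1.00 on casein (adjusted p = 0.00116). Of 19 mitotic genes 10 rose and 5 fell on casein, or 10 and 7 over the list alone (camera adjusted p = 0.371), and 6 rose and 6 fell on soy by both counts (camera adjusted p = 0.892). Mki67, a marker of dividing cells, rose by 0.49 on casein, the replication gene Mcm4 rose by 0.94 on soy (adjusted p = 6.26e-05), and the mitotic kinase gene Aurka fell by 0.60 on soy (adjusted p = 0.000295).

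Transcripts of neighbouring tissues were high in some arrays. Adam7, an epididymal gene, read 9.39 in soy with estradiol replicate 1 and 5.17 to 6.03 in the other arrays. Other epididymal transcripts were high in more arrays. Ces5a read 9.38 in casein replicate 1, 8.41 in soy replicate 2 and 8.81 in soy with estradiol replicate 1, Cd52 read 8.43, 7.76 and 8.95 in the same arrays, and Rnase12 read 7.42, 6.51 and 9.04. Acta1, the actin of skeletal muscle, read 10.37 in casein with estradiol replicate 2 and 4.99 to 6.24 in the other arrays. Myh6 read 7.88 to 8.56 in all 6 arrays with estradiol and 6.06 to 6.51 in the 6 without. Car3 read 5.02 to 5.58 in casein, 8.31 and 9.84 in casein with estradiol replicates 1 and 2, 9.71 in soy replicate 2, and 9.91 and 10.08 in soy with estradiol replicates 1 and 3.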
